A study of Mus musculus with 8 samples.

How the data were processed

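RNA was extracted from mouse embryonic fibroblasts with TRIzol and RNeasy columns, and strand-marked (dUTP) libraries were made from polyadenylated RNA, per the labels' protocols. Per the submitters' processing notes, the tools used were fastp 0.23.2, HISAT2 2.1.0, featureCounts of Subread 2.0.2 and DESeq2 1.34.0, with the mouse build mm10. The strand setting of the counting and the annotation release were not given in the sources used here, so reads of overlapping or antisense genes may not be separated. The authors deposited expected counts, that is estimated counts per gene that need not be whole, in 2 tables: one with the proliferating and n-Sen libraries and one with the n-Sen libraries in control and alkaline medium. Both held the same 54838 gene rows, and between 32.7% and 33.7% of the nonzero values of a library were fractional. The values were rounded to whole numbers before testing. Symbols and coordinates came from GENCODE vM21 on GRCm38, the build also called mm10, which gave a symbol for 54723 of the IDs. No columns of other samples were used.

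Libraries were grouped as the labels give them, with 2 in each of 4 groups. Total counts were 40608517 and 48247440 in proliferating cells, and 46645737 and 54183060 in n-Sen. They were 48801238 and 50467693 in control medium, and 41342558 and 45089805 in alkaline medium. The 10 most abundant genes took between 5.17% and 8.47% of a library and mitochondrial transcripts between 1.48% and 1.86%. Within groups, a chi-square of the counts over genes with at least 20 counts in the pair gave 7.39, 5.02, 6.88 and 4.63 per degree of freedom for proliferating, n-Sen, control and alkaline libraries.

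Genes were kept with edgeR's filterByExpr, scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The n-Sen and proliferating libraries were fitted on their own, as were the alkaline and control-medium libraries, and the comparison between tables came from a fit of all 8. The biological coefficient of variation was 0.0646, 0.0579 and 0.0618 in these fits. The SE of a log2 fold change was its absolute value divided by the square root of the F statistic. CPM used TMM-scaled library sizes. A gene with no count in a group was set against a floor of 3 counts over the group, and ratios on few counts were given a 95% counting interval. Intersections of called genes were tested with Fisher's exact test on the genes tested in both comparisons.

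A set of 34 gene lists was tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. They cover p53 targets, DNA replication and E2F targets, G2 and mitosis, SASP cytokines and chemokines, SASP proteases and matrix regulators, NF-kB targets, interferon response, glycolysis, hypoxia, pH and acid-base transport, V-ATPase, lysosome and autophagy, glutamine metabolism, cholesterol and fatty acid synthesis, the amino acid and unfolded protein responses, heat shock, NRF2 targets, collagens and matrix, TGF-beta and YAP targets, immediate early genes, oxidative phosphorylation, mitochondrial-encoded transcripts, cytosolic ribosomal proteins, replication-dependent histones, and markers of macrophages, endothelium, epithelium, adipocytes, muscle, cartilage and bone, neural and glial cells, and fibroblasts. Camera with an estimated correlation and fry were run beside it. The estimated correlation rests on 2 libraries per group, so that check has little power. A list that it did not call is therefore left undecided by it. In lists with a gene at 0 counts in one group, the median with that gene at its bound was the same as the median of fitted values.

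The groups, the tests, the gene lists, the alternatives and the rule for named genes were chosen before the data were examined. By that rule the text names, per comparison, the 10 higher and 10 lower genes of largest fold change among those called, with a mean of at least 10 CPM in the higher group, no overlap between groups and an ordinary symbol. It also names up to 4 members of smallest p of each described list with the members that moved the other way, 20 key genes of senescence and pH, and the 10 opposite and 5 same-direction genes with the largest product of fold changes under the same conditions in both comparisons. The aryl hydrocarbon receptor, Hox and hindlimb genes, the genes named for the comparison between tables and the list of other leukocyte genes were chosen later, after values had been seen. Some genes that the rule names are not reported here.

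The procedure was tested on simulated counts with 200 changed genes per comparison. For n-Sen against proliferating cells, 52.2% of the genes changed 1.5-fold, 76.1% of those changed 2-fold and 86.4% of those changed 4-fold were recovered with the right sign, and 9 of 19064 unchanged genes were called. For alkaline against control medium the shares were 65.7%, 82.1% and 90.9%, and 6 of 18929 unchanged genes were called. Of the 1.5-fold changes in genes at or under a mean of 5 CPM, 1 of 30 was recovered for n-Sen and 4 of 25 for alkaline medium, against 34 of 37 and 40 of 42 in genes over it. Camera called 1 of 10 unchanged lists of 30 genes in each comparison. The number of lists was raised to 100 after such a call had been seen, and 0 of 100 were then called in each comparison (4 at an unadjusted p under 0.05). The list raised 1.5-fold was called in every run. Simulated genes varied independently, so these runs do not test camera on lists of correlated genes. Far fewer genes were changed in them than were called in the data.

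Alternatives were DESeq2 1.42.0, limma-voom, edgeR with DESeq2's size factors or upper quartile scaling, no filter on low counts, a filter of at least 1 CPM in at least 2 libraries, a threshold of 1 on the absolute log2 fold change, a single fit of all 8 libraries, the replicate number as a block, and each library left out in turn. The list tests were also run without macrophage genes, an alternative chosen after the data were seen.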

Results

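Polyadenylated RNA was sequenced from mouse embryonic fibroblasts, primary connective tissue cells taken from embryos, in 8 libraries that fall into 4 groups of 2. The groups were proliferating cells, cells made senescent through nutlin3a (n-Sen), and n-Sen cells kept for 24 h in HEPES-buffered medium adjusted either to the control pH or to an alkaline one. Nutlin3a blocks the binding of MDM2 to p53 and so stabilises p53. Cells were first held in G2 with the CDK1 inhibitor RO3306, exposed to nutlin3a for 48 h, and then kept for 14 days in 100 nM of the PLK1 inhibitor BI-2536, which removes cells that still divide. Total counts ran from 40608517 (proliferating replicate 1) to 54183060 (n-Sen replicate 2). The 2 libraries of each group differed by more than sampling noise, with a chi-square per degree of freedom between 4.63 and 7.39, so none was counted as a repeat of another. The labels do not state separate cultures, so the p-values below measure only the spread between these samples, which may be technical. Expression is given as mean CPM ± SD (n = 2), fold changes as log2 values ± SE, and coordinates on mm10.

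The first comparison asks which transcripts differ between n-Sen and proliferating cells. Nutlin3a and 14 days of BI-2536 are recorded for the n-Sen cells and not for the proliferating ones. Senescence therefore cannot be told apart from these treatments and the time in culture. Genes of the cell cycle fell together: all 40 tested genes of G2 and mitosis and all 45 tested replication and E2F target genes were lower in n-Sen. Mki67, the proliferation antigen Ki-67, fell from 425 ± 15.7 to 8.26 ± 2.48 CPM, a log2 fold change of -5.70 ± 0.114. Cdkn1a, which encodes the CDK inhibitor p21 (chromosome 17, 29090976 to 29100727), rose from 215 ± 16.7 to 884 ± 4.58 CPM. Cdkn2a, the p16 and p19ARF locus (chromosome 4, 89274471 to 89294653), rose from 16.6 ± 0.614 to 325 ± 20.6 CPM. Lmnb1, which encodes lamin B1 and is commonly lost in senescence, fell from 173 ± 4.07 to 4.43 ± 0.251 CPM. Lysosome and autophagy genes rose in 38 of 41 cases and fell in 1, and collagens and matrix genes rose in 27 of 34 and fell in 5. Ribosomal protein genes fell in 41 of 41 cases, cholesterol synthesis genes fell in 21 of 25 and rose in 1, and markers of macrophages rose in 20 of 20. Camera called each of these lists at a preset correlation and none with an estimated correlation (adjusted p = 0.286, 0.153, 0.180, 0.339 and 0.205, in this order). The same held for both cell cycle lists (adjusted p = 0.153 for each with an estimated correlation). With 2 libraries per group this check has little power over 34 lists. Even for G2 and mitosis, with all 40 genes lower, its unadjusted camera p was 0.0154.

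Of 19264 genes tested, 6553 were higher and 6377 lower in n-Sen by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p under 0.05), of which 3313 and 2518 changed by at least 1 on the log2 scale. The libraries of the groups did not overlap for 83.4% of the genes, where chance gives 33.3%. Among genes reaching 10 CPM in either group, the steepest rises were those of Ppp2r2c, a regulatory subunit of protein phosphatase 2A, and of Hoxd13, a homeobox gene of distal limb patterning. Ppp2r2c (chromosome 5, 36868513 to 36955078) reached 10.7 ± 0.606 CPM in n-Sen and had no count in the proliferating libraries, a level at least 321-fold higher against a floor of 3 counts over that group. Hoxd13 (chromosome 2, 74668310 to 74671599) rose from 0.0407 ± 0.0575 to 25.4 ± 1.01 CPM. Ivl, the cornified envelope protein involucrin, had 2 counts in the proliferating libraries and 12.5 ± 1.66 CPM in n-Sen, a ratio of 569 with a 95% counting interval from 157 to 4710; this interval and the floor cover counting error only. Fcgr2b, an inhibitory Fc receptor of immune cells, Olfr78, Folh1, Snhg11, Scn3b, Elobl and the hypertrophic cartilage collagen Col10a1 also rose, Col10a1 from 7.12 ± 0.770 to 542 ± 8.99 CPM. The steepest fall was that of Crabp1, a retinoic acid binding protein (chromosome 9, 54764748 to 54773110), from 285 ± 9.37 to 0.607 ± 0.00236 CPM. Slc38a4, an amino acid transporter, fell from 198 ± 2.21 to 1.25 ± 0.223 CPM, and the division genes Mybl2, Ska1, Espl1, Kif15, Aunip and Mki67 fell with log2 fold changes between -6.61 and -5.63. Fndc3c1 fell too (-5.61 ± 0.231). Igf2os also fell (-7.65 ± 0.287), but it lies antisense to Igf2 and carries fractional counts in all 4 libraries, so its reads cannot be separated from those of Igf2 with certainty. Fcgr2b, Olfr78, Snhg11 and Col10a1 also overlap other annotated genes, as do Cdkn1a, Top2a, Prc1, Ctsd, Ctsb, Glb1, Spp1, Icam1, Sqstm1, Cxcl16, Col3a1, Fn1, Eln and Pdgfra below, which leaves their levels uncertain to that extent.

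Transcripts of mitosis had a median log2 fold change of -4.78. Top2a, which encodes topoisomerase II alpha, fell from 454 ± 4.06 to 13.1 ± 1.91 CPM, the mitotic cyclin Ccnb1 from 139 ± 1.37 to 4.30 ± 0.0646 CPM, and the cytokinesis genes Anln and Prc1 by 3.71 and 4.36 on the log2 scale. All 40 also passed when adjusted over the list alone. In camera, limma's competitive test with a preset correlation, the list was lower at an adjusted p of 2.18e-130, and had an adjusted p = 0.153 with an estimated correlation. Replication and E2F targets fell with a median of -3.44 (45 of 45 adjusted over the list alone; camera adjusted p 3.47e-69; adjusted p = 0.153 with an estimated correlation). Uhrf1, which maintains DNA methylation at replication, fell from 165 ± 2.71 to 3.80 ± 0.0589 CPM, and the helicase subunits Mcm2, Mcm3 and Mcm5 fell by 3.70, 4.21 and 4.84 on the log2 scale. The chromatin proteins Hmgb1 (-2.06 ± 0.059) and Hmgb2 (-4.89 ± 0.123) fell as well.

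Targets of p53 mostly rose. Of 35 tested, 28 rose, 3 fell and 4 did not pass, with the same 28 and 3 counted when adjusted over the list alone (median 1.02; camera adjusted p 1.20e-13; adjusted p = 0.153 with an estimated correlation). Perp, a desmosomal apoptosis effector, rose from 9.84 ± 1.32 to 182 ± 2.59 CPM, the BH3-only gene Pmaip1 (Noxa) from 29.9 ± 2.54 to 247 ± 2.92 CPM, and Trp53inp1 from 36.7 ± 2.38 to 183 ± 3.24 CPM. Mdm2, the p53 ubiquitin ligase, rose by 1.31 ± 0.049 and the CDK inhibitor gene Cdkn2b by 2.58 ± 0.065. The transcript of Trp53 itself was lower (-1.26 ± 0.065). The 3 targets that fell were Ckap2, Plk2 and Gtse1, of which Ckap2 and Gtse1 are known for roles at the mitotic spindle. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 1.88e-15 for Cdkn1a (2.04 ± 0.054), 3.44e-18 for Cdkn2a (4.29 ± 0.068) and 1.45e-11 for Trp53, and neither library of one group overlapped those of the other for any of them.

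Lysosome and autophagy genes, the targets of the transcription factor TFEB, rose in 38 of 41 cases, with 1 lower (Fnip2) and 2 not passing (39 and 1 adjusted over the list alone; median 1.02; camera adjusted p 1.09e-16; adjusted p = 0.286 with an estimated correlation). The aspartic protease gene Ctsd rose from 389 ± 5.74 to 1931 ± 58.8 CPM, Ctsb from 389 ± 14.8 to 1165 ± 48.4 CPM. Ctsf rose from 4.45 ± 0.633 to 51.3 ± 0.484 CPM. Glb1, which encodes the enzyme behind senescence-associated beta-galactosidase, rose by 0.85 ± 0.077. Subunits of the V-ATPase, the proton pump that acidifies lysosomes, rose in 18 of 19 cases and the other did not pass (18 adjusted over the list alone; median 0.72; camera adjusted p 6.07e-06; adjusted p = 0.384 with an estimated correlation). Atp6v0d1, Atp6v0e, Atp6v1a and Atp6v0a1 rose by 0.94 to 1.04 on the log2 scale. The macrophage list rose with both groups, and 2 of its genes, Ctss (2.78 ± 0.221 to 58.0 ± 4.89 CPM) and Cd68, are also in the lysosome list.

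Macrophage markers rose in 20 of 20 tested cases, also adjusted over the list alone, with a median of 4.27 (camera adjusted p 7.06e-32; adjusted p = 0.205 with an estimated correlation). Lyz2, which encodes lysozyme, rose from 25.3 ± 3.50 to 744 ± 31.4 CPM, the complement genes C1qa and C1qc from 1.91 ± 0.575 and 2.22 ± 0.255 to 68.8 ± 3.37 and 62.2 ± 2.72 CPM. Adgre1, the macrophage surface marker F4/80, rose from 1.18 ± 0.288 to 49.1 ± 1.83 CPM. Lyz1 of the same list had no count in proliferating cells and 6.95 ± 7.06 CPM in n-Sen, where the libraries differed widely. Fibroblast markers rose in 11 of 16 cases and fell in 5, the same counts adjusted over the list alone (median 0.60; camera adjusted p 0.00893; adjusted p = 0.242 with an estimated correlation). Among them the proteoglycan gene Dcn rose by 2.23 ± 0.090 and the growth factor receptor gene Pdgfra fell from 89.3 ± 5.48 to 9.98 ± 1.25 CPM. Epithelial markers fell in 6 of 10 cases, rose in 2 and did not pass in 2 (6 and 2 adjusted over the list alone; median -2.19; camera adjusted p 0.0128; adjusted p = 0.242 with an estimated correlation). The keratin genes Krt19, Krt18 and Krt7 and the mesothelial gene Msln fell by 4.15, 3.33, 1.81 and 2.96 on the log2 scale.

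**Figure D1:**
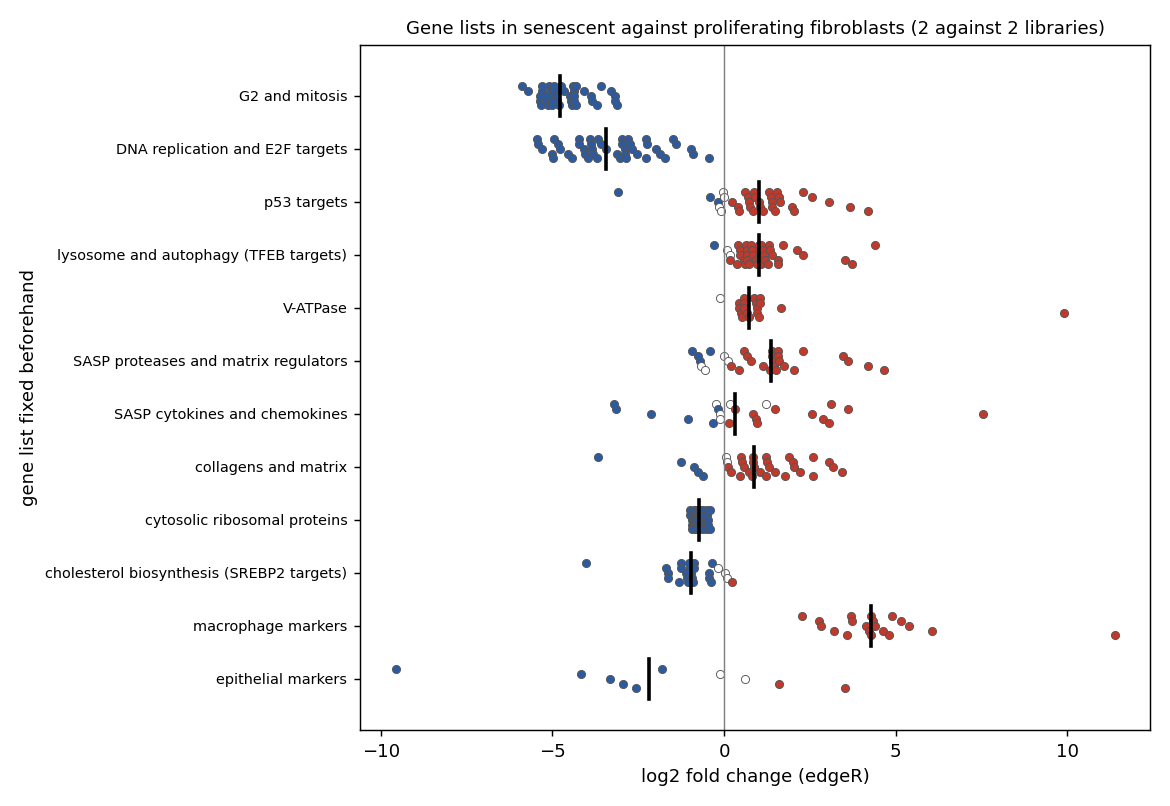
Log2 fold change of each tested gene (points) in n-Sen against proliferating cells for 12 gene lists fixed before the data were examined, with the list median as a bar; filled points passed edgeR's test (red higher, blue lower) and open points did not. Genes of G2 and mitosis lie furthest to the left (median -4.78) and macrophage markers furthest to the right (median 4.27).

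Secreted factors that are often part of the senescence-associated secretory phenotype (SASP) moved in both directions. Of 30 SASP proteases and matrix regulators, 22 rose, 4 fell and 4 did not pass (22 and 4 adjusted over the list alone; median 1.36; camera adjusted p 1.30e-16; adjusted p = 0.176 with an estimated correlation). Igfbp2, an insulin-like growth factor binding protein, rose from 71.7 ± 4.25 to 1319 ± 79.6 CPM, and Serpine2 from 59.9 ± 4.15 to 664 ± 3.50 CPM. The gelatinase gene Mmp2 rose from 167 ± 3.06 to 681 ± 0.232 CPM, and Spp1, which encodes osteopontin and is also abundant in macrophages, from 171 ± 7.69 to 845 ± 1.23 CPM. Mmp3 rose by 1.34 ± 0.334 from a low level of 1.12 ± 0.423 CPM. Of 23 SASP cytokines and chemokines, 12 rose, 6 fell and 5 did not pass, and the same 12 and 6 counts held adjusted over the list alone (median 0.31; camera adjusted p 0.224). Il1rn, the interleukin 1 receptor antagonist, rose by 3.13 ± 0.101, and the monocyte attractants Ccl7 and Ccl2 by 1.49 ± 0.083 and 0.96 ± 0.074. The fibroblast growth factor gene Fgf7 fell by 1.05 on the log2 scale. Interleukin 6 transcripts were few, with Il6 at 0.827 ± 0.134 and 1.56 ± 0.0961 CPM, and Cxcl1 fell from 1.90 ± 0.0957 to 0.206 ± 0.137 CPM.

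NF-kB targets went both ways: 7 of 25 rose, 9 fell and 9 did not pass, also adjusted over the list alone (median 0.012; camera adjusted p 0.495). In limma's fry the list moved upward on balance (adjusted p = 0.0153). The adhesion molecule gene Icam1 rose from 1.72 ± 0.162 to 48.8 ± 2.18 CPM, Cxcl16 by 2.92 ± 0.154 and Sqstm1 by 1.07 ± 0.050, Nfkb1 fell by 0.77 on the log2 scale, and the inhibitor gene Nfkbia did not pass (-0.14 ± 0.093). Interferon response genes rose in 19 of 26 cases, with 1 lower (Cgas) and 6 not passing (19 and 1 adjusted over the list alone; median 1.38; camera adjusted p 0.0272; adjusted p = 0.506 with an estimated correlation). Their levels stayed low: Bst2 rose from 5.52 ± 0.251 to 20.2 ± 0.844 CPM, and Ifit3, Parp14 and the RNA sensor gene Ddx58 rose by 2.82, 3.14 and 0.91. These changes of secreted, NF-kB and interferon genes stood beside the rise of the macrophage list by a median of 4.27. The calls of Il6 and Mmp3 depended on single libraries in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment: Il6 (adjusted p = 0.0214) did not pass without n-Sen replicate 1 (0.0991), n-Sen replicate 2 (0.0557) or proliferating replicate 2 (0.0969), nor in DESeq2 (0.124), and Mmp3 (adjusted p = 0.00195) did not pass without n-Sen replicate 2 (0.0942).

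Collagens and other matrix genes rose in 27 of 34 cases, with 5 lower and 2 not passing (27 and 5 adjusted over the list alone; median 0.86; camera adjusted p 2.47e-12; adjusted p = 0.153 with an estimated correlation). Fn1, which encodes fibronectin, rose from 5600 ± 8.86 to 20590 ± 378 CPM, Col3a1 from 282 ± 1.96 to 1713 ± 16.2 CPM. Col5a2 rose from 1202 ± 21.8 to 4096 ± 53.6 CPM, and the elastin gene Eln from 30.6 ± 3.46 to 252 ± 17.7 CPM. The 5 that fell were Fbln1, Vcan, Col6a1, Col6a2 and Col6a3. Cytosolic ribosomal protein genes fell in 41 of 41 cases, also adjusted over the list alone (median -0.74; camera adjusted p 3.68e-13; adjusted p = 0.180 with an estimated correlation), for example Rps2 from 2241 ± 122 to 1227 ± 12.7 CPM and Rpl3 from 1114 ± 5.12 to 587 ± 13.8 CPM. Rpl8 fell by 0.98. Replication-dependent histone genes, whose mRNAs normally lack a poly(A) tail, rose in 18 of 20 cases and fell in 2, also adjusted over the list alone (median 1.85; camera adjusted p 0.0111; adjusted p = 0.242 with an estimated correlation). Hist1h3b rose from 0.940 ± 0.00778 to 24.5 ± 0.0570 CPM and Hist1h2ab, Hist1h1e and Hist1h4a by 4.51, 3.77 and 3.35. These copies are near-identical and carried fractional counts, so their single values are uncertain.

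Cholesterol synthesis genes, the targets of SREBP2, fell in 21 of 25 cases, with 1 higher and 3 not passing (21 and 1 adjusted over the list alone; median -0.97; camera adjusted p 4.31e-09; adjusted p = 0.339 with an estimated correlation). Acat2 and Hmgcs1, which act in the first steps of the pathway, fell by 1.64 and 1.10 on the log2 scale. Glycolysis genes went both ways, with 9 of 26 higher, 13 lower and 4 not passing, also adjusted over the list alone (median -0.11; camera adjusted p 0.598). The lactate transporter genes Slc16a1 and Slc16a3 fell by 2.38 and 0.81, Eno1 and the lactate dehydrogenase gene Ldha by 0.71 and 0.62, while Bpgm rose by 2.06 ± 0.082 and the hexokinase gene Hk2 by 0.30 ± 0.058. Genes of pH and acid-base transport rose in 18 of 36 cases and fell in 10, also adjusted over the list alone (median 0.68; camera adjusted p 0.323). Among them the carbonic anhydrase genes Car5b and Car8 rose by 1.99 ± 0.135 and 1.47 ± 0.121 and the transporter chaperone gene Bsg by 0.63 ± 0.047.

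Across the 34 lists, camera called 21 in this comparison, 12 higher and 9 lower. With an estimated correlation it called 0 (8 at an unadjusted p under 0.05, lowest adjusted p 0.153), and fry, which tests whether a list's genes move on balance one way, called 30. The median, mean and test differed in sign for the unfolded protein response and for neural and glial markers. Fry alone called SASP cytokines, NF-kB targets, pH transport and adipocyte markers higher (adjusted p = 0.004, 0.0153, 0.00297 and 0.0117). It alone called NRF2 targets, oxidative phosphorylation and endothelial, muscle and cartilage markers lower (fry adjusted p = 0.0413, 0.0409, 0.0184, 0.0405 and 0.0241).

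The second comparison, n-Sen cells in alkaline against control medium, addresses the stated purpose of the series, the transcriptional change when senescent cells are placed under alkaline conditions. The transcripts lower in alkaline than in control medium included those of oxidative stress defence: 20 of 28 NRF2 target genes were lower and 0 higher. Against the n-Sen group of the first comparison, 20 of the 28 were higher in control medium (median 0.46). In alkaline medium against that group, 10 were higher and 3 lower (median 0.060). Medium and count table cannot be told apart in these 2 contrasts. Cholesterol synthesis genes rose in alkaline against control medium in 19 of 25 cases. Il11, a cytokine of the interleukin 6 family (chromosome 7, 4772373 to 4782859), rose from 25.0 ± 1.61 to 86.4 ± 1.42 CPM. Vegfa, the vascular endothelial growth factor gene (chromosome 17, 46016993 to 46032369), rose from 188 ± 2.98 to 428 ± 0.204 CPM. Cdkn1a (940 ± 36.2 and 929 ± 6.32 CPM) and Cdkn2b (132 ± 7.69 and 133 ± 1.39 CPM) did not pass, and neither did Mki67. Cdkn2a did not pass with all libraries but did without alkali replicate 1 (adjusted p = 0.0189, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 35 p53 targets, 4 rose and 10 fell. Markers of macrophages fell in 10 of 20 cases. With an estimated correlation camera called none of the NRF2, cholesterol and macrophage lists (adjusted p = 0.326 for each).

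Of 19129 genes tested, 1833 were higher and 1995 lower in alkaline medium by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 184 and 344 changing by at least 1 on the log2 scale. Libraries of the groups did not overlap for 56.8% of the genes, against 33.3% by chance, and the median absolute log2 fold change of called genes was 0.39, compared with 0.89 in the first comparison. Among genes reaching 10 CPM, the steepest rises were those of the semaphorin gene Sema4f, the cadherin gene Cdh6 (22.8 ± 0.611 to 88.5 ± 7.90 CPM), Olfm2, the scaffold gene Whrn, Il11, Prss35, the hyaluronan synthase gene Has2 (30.04 ± 0.314 to 91.8 ± 4.23 CPM) and Gfpt2, with log2 fold changes from 1.58 to 1.97. The steepest falls were those of Pi15, a peptidase inhibitor (21.7 ± 1.36 to 1.99 ± 0.338 CPM), the cytokine gene Tslp (13.1 ± 1.16 to 2.12 ± 0.856 CPM), Gas1, the activin subunit gene Inhbb, Ptx3, Rspo2, Adm, Cyp1a1, Arhgap6 and Egr3, with log2 fold changes from -3.44 to -1.68. Has2, Pi15, Gas1 and Arhgap6 overlap other annotated genes, as do Cyp51, Slc2a1, Pkm, Slc4a2, Vcam1, Tnfaip2, Ephx1 and Npc1 among the genes named for this comparison, so their levels are uncertain to that extent.

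NRF2 targets fell in 20 of 28 cases (23 adjusted over the list alone), and the remaining 8 did not pass (median -0.35; camera adjusted p 6.41e-18; adjusted p = 0.326 with an estimated correlation). Nqo1, a quinone reductase (chromosome 8, 107388225 to 107403206), fell from 250 ± 4.32 to 94.6 ± 4.96 CPM, Gclc, the catalytic subunit of glutathione synthesis, from 88.6 ± 3.63 to 40.6 ± 0.454 CPM. Gsta4 fell by 1.37 and the thioredoxin reductase gene Txnrd1 by 0.49 on the log2 scale. Cholesterol synthesis genes rose in 19 cases (21 adjusted over the list alone), with 0 lower (median 0.24; camera adjusted p 1.80e-09; adjusted p = 0.326 with an estimated correlation). Among them Cyp51 and Dhcr7, enzymes of the later steps, rose by 0.42 ± 0.046 and 0.79 ± 0.100.

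Glycolysis genes rose in 9 of 26 cases and fell in 1, also adjusted over the list alone (median 0.12; camera adjusted p 0.000949; adjusted p = 0.326 with an estimated correlation). The glucose transporter gene Slc2a1 rose from 106 ± 5.55 to 152 ± 9.97 CPM, Hk2 from 92.3 ± 6.002 to 137 ± 8.49 CPM, Slc16a3 from 22.3 ± 0.0613 to 36.4 ± 0.184 CPM and Pkm by 0.23 ± 0.035, while Ldha did not pass (0.092 ± 0.039). In DESeq2 with Benjamini-Hochberg adjustment Ldha did pass (0.097, adjusted p = 0.0414). V-ATPase genes rose in 7 of 19 cases and fell in 2 (9 and 2 adjusted over the list alone; median 0.11; camera adjusted p 0.00714; adjusted p = 0.326 with an estimated correlation), led by Atp6v1g1, Atp6v1d, Atp6v0a2 and Atp6v0d1 (0.54, 0.33, 0.26 and 0.22). Of 37 genes of pH and acid-base transport, 6 rose, 2 fell and 29 did not pass, also adjusted over the list alone, and the list was not called (camera adjusted p 0.283), with a median of -0.018 against a mean of 0.050. The bicarbonate transporter genes Slc4a2 and Slc4a7 rose by 0.37 ± 0.045 and 0.33 ± 0.055, and the sodium-proton exchanger gene Slc9a5 by 0.66 ± 0.113.

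Targets of TGF-beta and YAP rose in 12 of 27 cases and fell in 3 (13 and 4 adjusted over the list alone; median 0.081; camera adjusted p 1.59e-08; adjusted p = 0.326 with an estimated correlation). Il11 is in this list, and Skil, a feedback repressor of TGF-beta signalling, rose from 122 ± 4.09 to 214 ± 5.604 CPM, Pmepa1 by 0.53 ± 0.039 and the tissue factor gene F3 by 0.56 ± 0.042. The 3 that fell were Tgfb2, Lats2 and Ccn1. SASP cytokines and chemokines split, with 6 of 25 higher, 8 lower and 11 not passing (8 and 11 adjusted over the list alone); their median (-0.25) and mean (-0.39) were negative while camera leaned upward without passing (adjusted p 0.285). Vegfa, Il11 and Lif rose by 1.19 ± 0.042, 1.79 ± 0.064 and 0.99 ± 0.056, and Il1rn fell from 57.2 ± 7.37 to 19.9 ± 0.485 CPM. Il6 (0.54 ± 0.194), Ccl2 (0.14 ± 0.058) and Cxcl1 (-1.12 ± 0.482) did not pass. SASP proteases and matrix regulators also split, 10 of 30 higher and 11 lower (10 and 12 adjusted over the list alone), and camera called the list lower (median -0.065; adjusted p 0.00205; adjusted p = 0.326 with an estimated correlation). The urokinase gene Plau fell from 311 ± 5.98 to 139 ± 1.76 CPM, Igfbp2 from 1240 ± 23.6 to 699 ± 6.38 CPM. Serpine2 and Igfbp4 fell by 0.72 and 0.68, whereas Mmp3 did not pass (-0.16 ± 0.202). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment Il6 (adjusted p = 0.0528) passed with DESeq2's size factors (0.0498), with no filter on low counts (0.0405) and with a filter of at least 1 CPM (0.047). It also passed without alkali replicate 1 (adjusted p = 0.0401) or control replicate 1 (0.0111) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and Ccl2 (adjusted p = 0.0875) passed without alkali replicate 2 (0.0143).

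NF-kB targets fell in 8 of 26 cases and rose in 3 (11 and 4 adjusted over the list alone; median -0.067; camera adjusted p 0.0376; adjusted p = 0.332 with an estimated correlation). The adhesion molecule gene Vcam1 fell from 154 ± 4.66 to 64.0 ± 4.85 CPM, Tnfaip2 and Icam1 fell by 0.84 and 0.50. Ptgs2, which encodes cyclooxygenase 2, rose from 968 ± 12.8 to 1605 ± 47.5 CPM; Nfkbia did not pass (-0.09 ± 0.085). Interferon response genes fell in 7 of 27 cases and rose in 0, also adjusted over the list alone (median -0.47; camera adjusted p 0.0093; adjusted p = 0.326 with an estimated correlation), with Ddx58, Ifit2, Bst2 and Ifit3 lower by 0.49 to 0.84. Macrophage markers fell beside these groups in 10 of 20 cases (11 adjusted over the list alone; median -0.28; camera adjusted p 1.45e-05; adjusted p = 0.326 with an estimated correlation). Mrc1 fell from 13.9 ± 0.682 to 5.14 ± 0.834 CPM, Adgre1 from 55.5 ± 3.15 to 37.2 ± 0.495 CPM, and Ms4a7 and C1qc fell by 0.75 and 0.34. Lysosome and autophagy genes rose in 11 of 41 cases and fell in 5 (12 and 7 adjusted over the list alone; median 0.016; camera adjusted p 0.568), among them Npc1 (0.33 ± 0.063), Cd63 (0.17 ± 0.042), Hexa (-0.20 ± 0.044) and Gpnmb (-0.19 ± 0.043). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment Cd63 (adjusted p = 0.00526) did not pass without alkali replicate 1 (0.181).

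Fibroblast markers fell in 9 of 16 cases and rose in 3 (9 and 4 adjusted over the list alone; median -0.18; camera adjusted p 0.00126; adjusted p = 0.332 with an estimated correlation). The mesenchymal transcription factor gene Prrx1 fell from 320 ± 1.60 to 162 ± 4.22 CPM and Thy1 by 0.57 on the log2 scale, whereas Col1a1 and Pdgfrb rose by 0.42 ± 0.040 and 0.41 ± 0.044. Adipocyte markers fell in 4 of 9 cases, with Lpl, Pparg, Plin4 and Acsl1 lower by 0.36 to 1.16 (4 adjusted over the list alone; median -0.24; camera adjusted p 0.0505). Plin4 and Acsl1 depended on single libraries and on the method: in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.00624 and 0.0295, and without alkali replicate 1 it was 0.106 and 0.109, while Acsl1 also did not pass without control replicate 2 (0.299). With all libraries, neither passed in DESeq2 with Benjamini-Hochberg adjustment (adjusted p = 0.357 and 0.132). Unfolded protein response genes rose in 7 of 25 cases and fell in 1, Crebrf, also adjusted over the list alone (median 0.072; camera adjusted p 0.0505). Xbp1, Herpud1 and Edem1 rose by 0.34, 0.39 and 0.25. Replication-dependent histone genes rose in 3 of 20 cases, also adjusted over the list alone (median 0.51; camera adjusted p 0.0168; adjusted p = 0.332 with an estimated correlation). These were Hist1h3b, Hist1h2ab and Hist1h3c (0.64, 0.76 and 1.04), while Hist1h4a did not pass (0.55 ± 0.200).

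Among p53 targets, 4 of 35 rose, 10 fell and 21 did not pass (6 and 11 adjusted over the list alone; median -0.045; camera adjusted p 0.311). Pmaip1 rose from 298 ± 4.22 to 480 ± 23.6 CPM and Mdm2 by 0.16 ± 0.039, and Ephx1, Perp and the death receptor gene Fas fell by 0.37, 0.37 and 0.66. Trp53 (0.23 ± 0.056), Lmnb1 (0.55 ± 0.165) and Glb1 (0.17 ± 0.061) rose slightly. Cdkn2a (-0.099 ± 0.048), Mki67 (-0.19 ± 0.142), Hmgb1 (-0.10 ± 0.063) and Hmgb2 (-0.52 ± 0.222) did not pass. Of 40 genes of G2 and mitosis, 2 fell, Anln and Kif23 (-0.38 ± 0.095 and -0.86 ± 0.225), and 38 did not pass, also adjusted over the list alone (median -0.063; camera adjusted p 0.529). Top2a (-0.36 ± 0.134) and Foxm1 (0.34 ± 0.139) did not pass. Several of these calls depended on single libraries in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Mdm2 did not pass without alkali replicate 2 (adjusted p = 0.074), Kif23 without control replicate 1 (0.0643), Lmnb1 without alkali replicate 1 (0.0746) or control replicate 2 (0.23), and Glb1 without alkali replicate 1 (0.484) or control replicate 1 (0.141). With all libraries, Glb1, Lmnb1 and Kif23 did not pass in DESeq2 with Benjamini-Hochberg adjustment (adjusted p = 0.103, 0.109 and 0.0683). Glb1 also did not pass in limma-voom (adjusted p = 0.0531), nor in edgeR's test with upper quartile scaling (0.0604) or in a single fit of all 8 libraries (0.0913). Conversely, by the same edgeR test with Benjamini-Hochberg adjustment, Cdkn2a and Hmgb2 passed without alkali replicate 1 (adjusted p = 0.0189 and 0.0153), Foxm1 without alkali replicate 1 (0.00949) and Top2a without control replicate 1 (0.0323). Top2a and Foxm1 also passed in edgeR's fit of all 8 libraries (adjusted p = 0.0216 and 0.0376). The signs of Cdkn1a (-0.016 ± 0.039) and Cdkn2b (0.011 ± 0.050) turned without control replicate 2 (0.024) and control replicate 1 (-0.046).

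**Figure D2:**
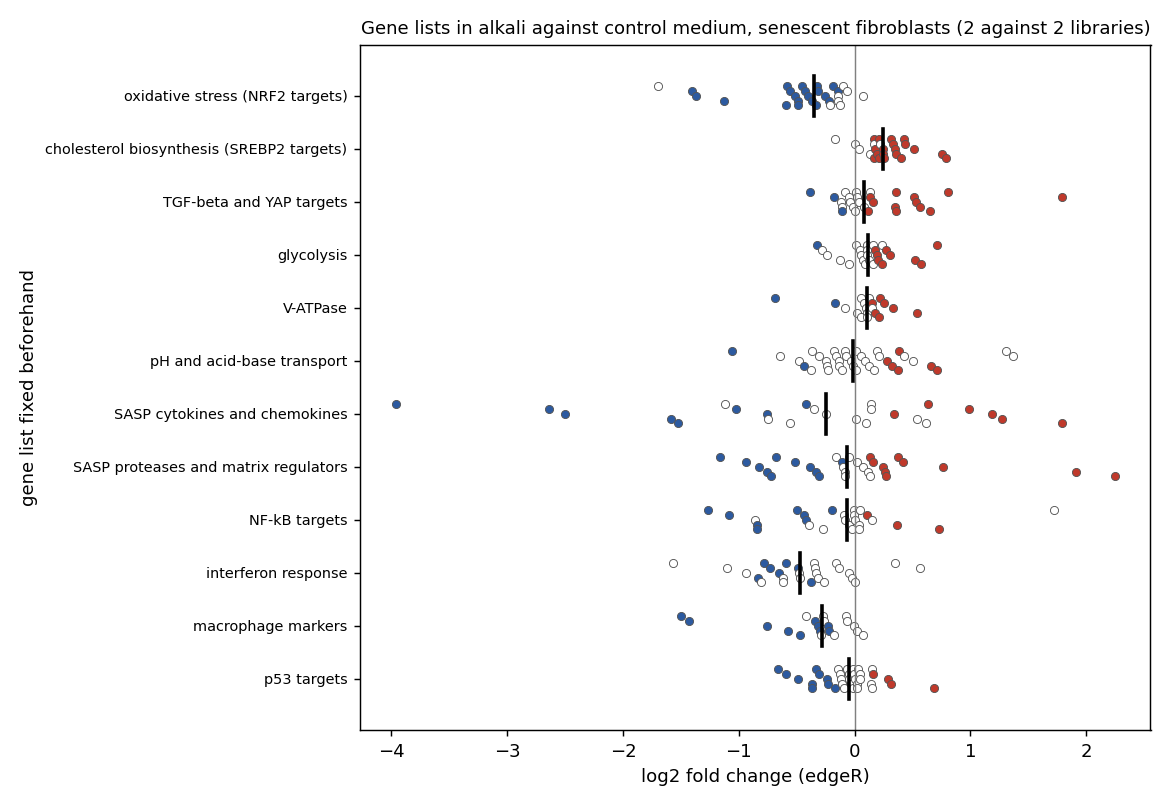
Log2 fold change of each tested gene (points) in alkaline against control medium for 12 gene lists fixed before the data were examined, with the list median as a bar; filled points passed edgeR's test (red higher, blue lower) and open points did not. NRF2 targets lie to the left of 0 (median -0.35) and cholesterol synthesis genes to the right (median 0.24).

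Across the 34 lists, camera called 11 in this comparison, 5 higher and 6 lower. With an estimated correlation it called 0 (2 at an unadjusted p under 0.05, lowest adjusted p 0.326), and fry called 14. Median, mean and test differed in sign for SASP cytokines and chemokines, hypoxia targets, pH and acid-base transport, fatty acid synthesis, ATF4 targets, mitochondrial-encoded transcripts, and endothelial, epithelial and muscle markers. Fry alone called p53 targets and adipocyte markers lower (adjusted p = 0.0255 for each) and heat shock genes higher (fry adjusted p = 0.0282).

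**Figure D3:**
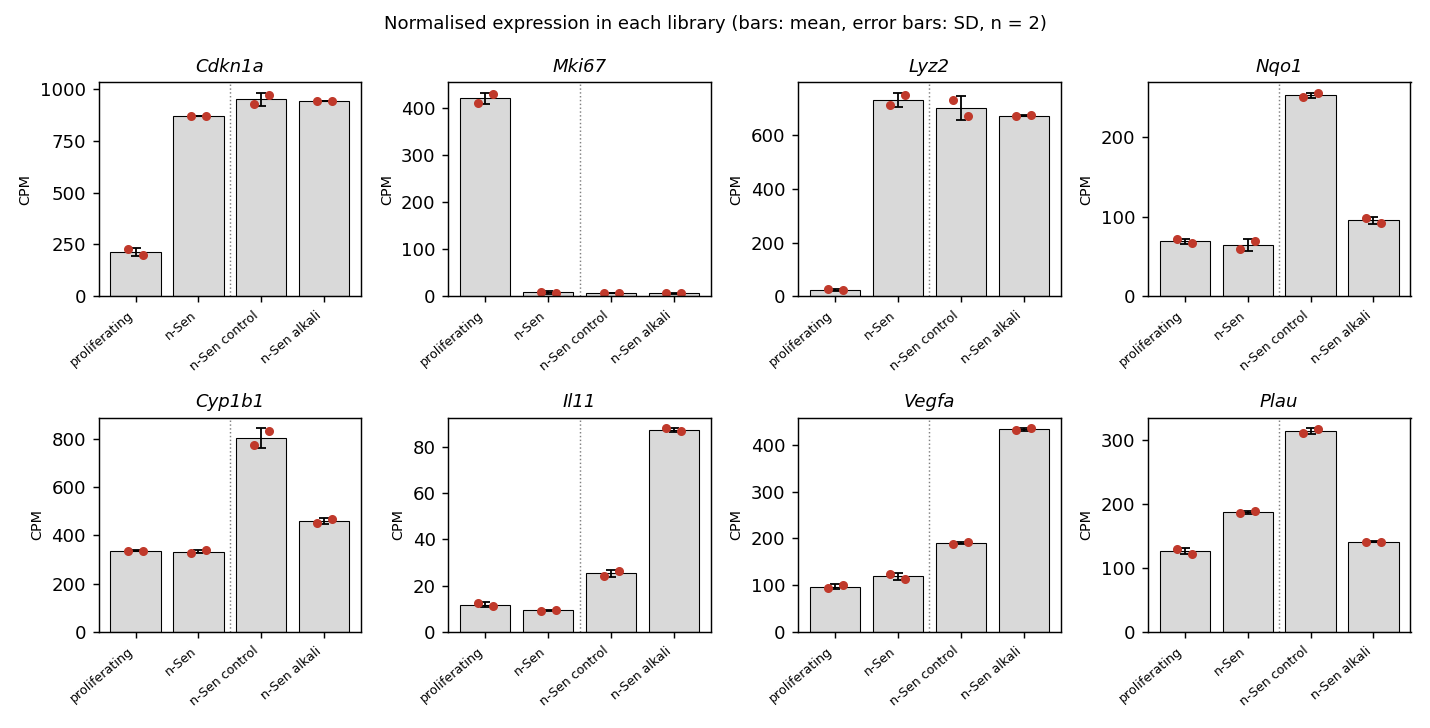
CPM of 8 genes in each library (points), with group means as bars and SD as error bars (n = 2); a dotted line parts the groups that come from separate count tables. Il11 and Vegfa stand highest in alkaline medium, and Nqo1, Cyp1b1 and Plau stand highest in control medium.

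Whether alkaline medium moved the genes that differ between n-Sen and proliferating cells was asked over 18484 genes. These were tested in both comparisons, which share no library. Genes higher in n-Sen and lower in alkaline medium numbered 1126, where independent lists would share 695.8 (odds ratio 2.73, 95% interval 2.49 to 3.01, Fisher's exact test across genes, p = 5.23e-97). Genes lower in n-Sen and higher in alkaline medium numbered 649, against 592.6 for independent lists (odds ratio 1.17, 1.05 to 1.29, Fisher's exact test, p = 0.00312). A further 778 were higher in both, against 634.6 (odds ratio 1.45, 1.31 to 1.60, Fisher's exact test, p = 2.25e-13), and 514 were lower in both, against 649.7 (odds ratio 0.692, 0.621 to 0.769, Fisher's exact test, p = 3.00e-12). With DESeq2 each of these counts was smaller. There were 790 genes higher in n-Sen and lower in alkaline medium and 465 the other way. A further 623 were higher in both and 339 lower in both. With an absolute log2 fold change of at least 1 in each comparison, fewer genes were shared. Of those lower in n-Sen, 29 were higher and 49 lower in alkaline medium. Of those higher in n-Sen, 56 were higher and 151 lower. Over all genes at that threshold, 184 were higher and 344 lower in alkaline medium. The 29 against 49 therefore shows no reversal by itself. In all, without that threshold, 1775 genes moved in opposite directions and 1292 in the same direction, 57.9% opposite. Genes are not independent replicates, so these p-values describe the lists and not the conditions. The counts for independent lists also assume that every gene is equally likely to be called. Changes of genes at low levels were recovered less often in simulated counts, and both groups of the alkaline comparison were n-Sen cells. Genes higher in n-Sen exceeded those counts in both directions, so the excess common to both cannot be told apart from easier detection. The excess was larger for genes lower in alkaline medium (odds ratio 2.73 against 1.45). Among genes lower in n-Sen, those higher in alkaline medium were in excess and those lower were too few (1.17 against 0.692). Whether detection also differs by direction was not tested.

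Opposite fold changes were ranked by their product among genes called in both comparisons with at least 10 CPM in the higher group of each. The first 10 were Folh1, Olfr78, Prelp, Palmd, Gda, Ppp2r2c, Pamr1, Nkain4, Il1rn and Ms4a7, each higher in n-Sen and lower in alkaline medium. Ppp2r2c ranked 6 by a fitted change from 0 counts, and 15 at its bound of 321-fold. With that bound Has2 took rank 10, and it was lower in n-Sen (-2.71) and higher in alkaline medium (1.61). Below the minimum level of 10 CPM, 56 further genes had a larger product of fitted changes than Ms4a7. Prelp, a leucine-rich matrix proteoglycan (chromosome 1, 133910304 to 133921414), rose from 10.3 ± 0.131 to 272 ± 0.406 CPM in n-Sen and fell from 245 ± 21.1 to 96.1 ± 4.08 CPM in alkaline medium. Folh1, a zinc peptidase, rose from 0.0688 ± 0.0399 to 13.7 ± 1.14 CPM and fell from 14.1 ± 3.16 to 5.34 ± 0.199 CPM, and Ms4a7 is one of the macrophage markers. The fall of Ppp2r2c in alkaline medium did not pass without control replicate 1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.133, against 0.00652 with all libraries). At the same minimum level the largest products of changes in the same direction were those of Igf2, Wnt9a, H19, Whrn and Ptx3, and below it 43 further genes had a larger product of fitted changes than Ptx3. Igf2, the imprinted insulin-like growth factor gene, fell from 609 ± 28.0 to 15.3 ± 1.29 CPM and then from 18.8 ± 0.984 to 9.42 ± 0.471 CPM. Its imprinted neighbour H19, which like Igf2, Prelp, Palmd and Nkain4 overlaps other annotated genes, fell from 757 ± 14.6 to 63.6 ± 9.31 CPM and from 102 ± 30.2 to 44.1 ± 8.34 CPM. The Wnt ligand gene Wnt9a rose from 3.32 ± 0.523 to 24.2 ± 2.73 CPM and from 19.7 ± 1.23 to 58.5 ± 2.96 CPM.

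As sets, the 6499 genes higher in n-Sen leaned lower in alkaline medium without passing (camera p = 0.0783, median log2 fold change -0.050; p = 0.112 with an estimated correlation), and the 6068 genes lower in n-Sen leaned higher without passing (camera p = 0.255, median 0.018; p = 0.0613 with an estimated correlation). Across genes the fold changes of the comparisons had a Pearson correlation of -0.115 and a Spearman correlation of -0.119. The Pearson value was -0.0358 with DESeq2, -0.0338 with no filter on low counts and -0.0763 without alkali replicate 2.

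**Figure D4:**
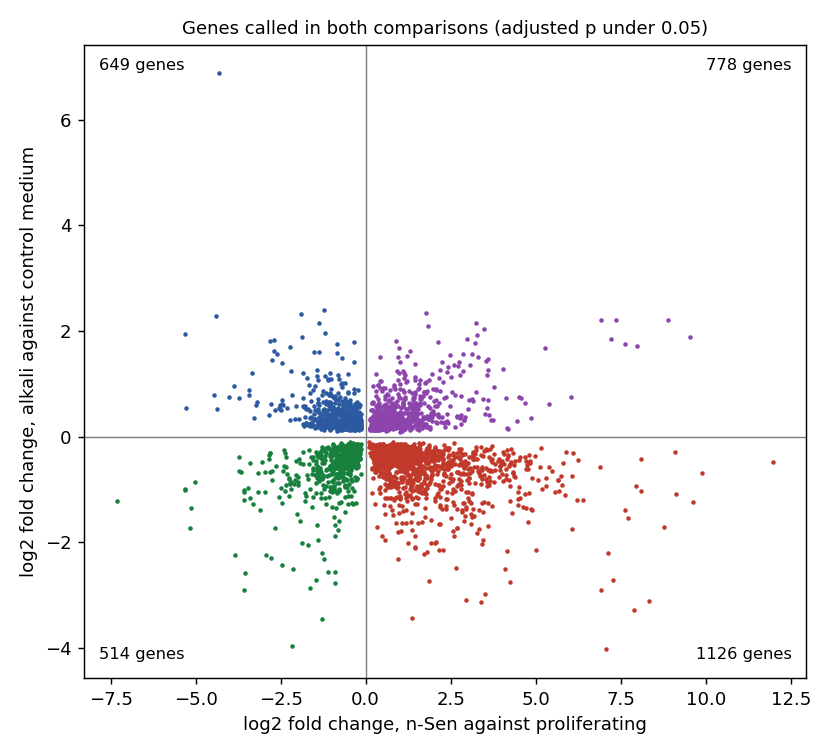
Log2 fold change in alkaline against control medium (y axis) and in n-Sen against proliferating cells (x axis) for the genes called in both comparisons, one point per gene. The quadrant of genes higher in n-Sen and lower in alkaline medium holds 1126, against 778 higher in both, 649 lower in n-Sen and higher in alkaline medium, and 514 lower in both.

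The third comparison set n-Sen cells in control medium against the n-Sen group of the first comparison. These groups lie in separate count tables, and the labels do not say whether the n-Sen group was also held in the buffered medium, so medium and table cannot be told apart. Of 20215 genes tested in a joint fit of all 8 libraries, 1250 were higher and 1003 lower in the control-medium libraries by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 52.0% did not overlap (33.3% by chance). Targets of the aryl hydrocarbon receptor, chosen here after their values were seen, were all higher: Cyp1a1, a xenobiotic-metabolising cytochrome, at 44.0 ± 4.56 against 0.0614 ± 0.0345 CPM, Cyp1b1 at 807 ± 43.8 against 332 ± 7.26 CPM, the receptor's repressor Ahrr at 22.3 ± 0.748 against 7.29 ± 0.848 CPM, Tiparp at 98.3 ± 1.84 against 25.1 ± 0.182 CPM, and Nqo1 at 253 ± 4.11 against 64.7 ± 7.44 CPM. The NRF2 targets Hmox1, Txnrd1, Srxn1 and Gclc, seen first as well, were higher by 1.74, 1.22, 0.95 and 0.90 on the log2 scale. Of 20 macrophage markers, 0 were higher and 2 lower (median -0.055), and Lyz2 (-0.059 ± 0.058) and Adgre1 (0.22 ± 0.076) did not pass. Of 50 further leukocyte genes, a list chosen after values were seen, 10 were higher and 5 lower (median 0.035). The counts fell by over 1.5 times with any library left out: to 816 higher and 452 lower without control replicate 1, 813 and 569 without control replicate 2, 731 and 450 without n-Sen replicate 1, and 781 and 521 without n-Sen replicate 2.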

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

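The comparison of alkaline medium with n-Sen and the list tests without macrophage genes were chosen after the results were seen. In simulated counts 1.5-fold changes of genes at or under 5 CPM were recovered in 1 of 30 and 4 of 25 cases, so most such changes could be missed. Where a library is left out the lone sample is assumed to vary like the other group. At an absolute log2 fold change of at least 1 the counts were 3313 higher and 2518 lower in n-Sen. In alkaline medium they were 184 and 344. The shared genes numbered 56 higher in both, 151 higher in n-Sen and lower in alkaline medium, 29 lower and higher, and 49 lower in both. Fewer genes pass such a threshold by construction. More genes fell than rose in alkaline medium at it, so the last 2 counts show no reversal by themselves. Upper quartile scaling gave 7257 higher and 5721 lower genes in n-Sen (55.9% higher, against 50.7%) and 1707 and 2114 in alkaline medium (44.7%, against 47.9%). By DESeq2, 623 genes were higher in both comparisons and 339 lower in both. It gave 790 genes higher in n-Sen and lower in alkaline medium, and 465 the other way. The correlation of fold changes across genes was -0.0358 with DESeq2 and -0.0338 with no filter on low counts, and ranged from -0.112 to -0.0763 with a library left out. In the comparison of control medium with n-Sen, leaving out a library gave 731 to 816 higher and 450 to 569 lower genes. Camera with an estimated correlation called 0 lists in both main comparisons, where the preset called 21 and 11, and by fry the senescence sets moved in alkaline medium with p = 0.0203 (higher in n-Sen) and 0.0377 (lower in n-Sen). Beyond these constructions the cause was not tested.

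Of the named genes, 145 of 152 in n-Sen, 116 of 135 in alkaline medium and 10 of 11 in the comparison between tables had one direction and one side of the threshold in every alternative run, as did 4 and 18 of the 34 lists. Values that turned sign lay within 0.089 of 0 and none of them passed. For n-Sen against proliferating cells, Cyp1b1 was at 0.001 with DESeq2's size factors, 0.006 with DESeq2, 0.012 with no filter, 0.089 with upper quartile scaling, 0.011 with at least 1 CPM, and between -0.030 and 0.026 with a library left out. Nqo1 was at 0.006 with upper quartile scaling and between -0.215 and 0.032 with a library left out, and the -0.215, without n-Sen replicate 2, passed (edgeR adjusted p 0.0438). With a library left out, Cdkn1a lay between -0.054 and 0.024 and Cdkn2b between -0.046 and 0.072 in alkaline medium, and Lyz2 between -0.121 and 0.004 in control medium against n-Sen.

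With the replicate number as a block, 6455 genes were higher and 6271 lower in n-Sen and 2056 and 2254 in alkaline medium, the 4 overlaps held 849, 1237, 729 and 577 genes, and the correlation across genes was -0.114. The deviations of same-numbered libraries correlated at -0.00305 over 19264 genes for n-Sen and proliferating cells (-0.0562, -0.103 and -0.201 over genes above 1, 3 and 5 log2 CPM) and at 0.00679 for alkaline and control medium, so the numbers were not taken to pair the samples. Under the block the mitochondrial-encoded list no longer passed in n-Sen (adjusted p 0.0502). In alkaline medium the block brought camera's calls from 11 lists to 14, adding the unfolded protein response (adjusted p 0.0407), adipocyte (0.0337) and neural and glial lists (0.044), and edgeR's calls of Il6 (adjusted p 0.0266), Top2a (0.0477) and Hist1h4a (0.0476). The first 2 of these lists also passed with DESeq2's size factors (camera adjusted p 0.0456 and 0.0478).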

Other observations

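The tests of fibroblast share, of Hox silencing, of body region and of the control libraries were chosen after the result was seen. The list of further leukocyte genes was also chosen after values were seen. Several gene groups of n-Sen cells have not yet been described. Heat shock genes fell in 13 of 20 cases and rose in 4 (13 and 5 adjusted over the list alone; median -0.66; camera adjusted p 0.0006; adjusted p = 0.214 with an estimated correlation). The chaperone genes Fkbp4 and Hspd1 fell by 2.39 and 1.32, with the lens chaperone gene Cryab higher by 2.23 ± 0.061. Immediate early genes fell in 19 of 31 cases and rose in 4 (19 and 5 adjusted over the list alone; median -0.50; camera adjusted p 0.0128; adjusted p = 0.242 with an estimated correlation). Myc fell from 88.0 ± 1.57 to 33.6 ± 0.459 CPM and Jun from 181 ± 4.75 to 84.3 ± 1.49 CPM. Glutamine metabolism fell in 9 of 15 cases and rose in 2, also adjusted over the list alone (median -0.56; camera adjusted p 0.00112; adjusted p = 0.220 with an estimated correlation). The glutamine transporter gene Slc1a5 fell from 66.5 ± 0.748 to 13.2 ± 0.390 CPM. Fatty acid synthesis fell in 11 of 14 cases and rose in 2, also adjusted over the list alone (median -0.58; camera adjusted p 0.000321; adjusted p = 0.321 with an estimated correlation). Fasn fell from 675 ± 8.36 to 315 ± 10.4 CPM. Hypoxia targets rose in 17 of 25 cases and fell in 3, also adjusted over the list alone (median 0.56; camera adjusted p 0.00391; adjusted p = 0.226 with an estimated correlation). The lysyl oxidase gene Loxl2 rose from 294 ± 12.97 to 1102 ± 12.9 CPM. TGF-beta and YAP targets rose in 18 of 27 cases and fell in 6, also adjusted over the list alone (median 0.27; camera adjusted p 0.000286; adjusted p = 0.205 with an estimated correlation). Tgfb2 rose from 28.5 ± 3.93 to 191 ± 5.20 CPM; Itgb2 of this list, a leukocyte integrin, rose by 4.84 ± 0.170 beside the macrophage markers. Mitochondrial-encoded transcripts rose in 11 of 15 cases and fell in 2 (11 and 2 adjusted over the list alone; median 0.23; camera adjusted p 0.0281; adjusted p = 0.611 with an estimated correlation).

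Beside the uncalled lists described above, camera did not call NRF2 targets in n-Sen (7 higher, 16 lower of 28, adjusted p 0.127) or ATF4 targets (14, 12 of 31, 0.598). Nor did it call the unfolded protein response (11, 10 of 25, 0.884, median -0.059, mean 0.136) or oxidative phosphorylation (7, 22 of 41, 0.181). The same held for markers of endothelium (2, 3 of 8, 0.495), adipocytes (3, 3 of 9, 0.080), muscle (2, 7 of 10, 0.397), cartilage and bone (2, 6 of 11, 0.163) and neural cells (4, 5 of 12, 0.877). In alkaline medium, immediate early genes went both ways, 8 of 31 higher and 16 lower (10 and 17 adjusted over the list alone; camera adjusted p 0.0546), with Egr1 down from 131 ± 5.86 to 55.7 ± 2.47 CPM and Ier3 up by 0.65 ± 0.048. Collagens and matrix genes rose in 10 of 34 cases and fell in 14 (13 and 15 adjusted over the list alone; camera adjusted p 0.107), with Eln and Col6a1 lower by 0.87 and 0.74. Camera did not call E2F targets (3 higher, 0 lower of 45; adjusted p 0.136), hypoxia targets (9, 2 of 25; 0.0668), glutamine metabolism (4, 2 of 15; 0.223), fatty acid synthesis (3, 3 of 14; 0.538), ATF4 targets (4, 4 of 31; 0.449), heat shock (5, 0 of 20; 0.0668), mitochondrial-encoded transcripts (2, 0 of 15; 0.449), ribosomal proteins (0, 1 of 41; 0.486) or markers of endothelium (0, 0 of 8; 0.975), epithelium (2, 1 of 9; 0.283), muscle (1, 2 of 8; 0.376), cartilage and bone (3, 4 of 11; 0.418) and neural cells (1, 3 of 9; 0.0547). Of 41 oxidative phosphorylation genes edgeR's test called 0 (camera adjusted p 0.723).

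Macrophage markers rose in n-Sen cells by a median of 4.27, with Lyz2 at 744 CPM, C1qa at 68.8 CPM and Adgre1 at 49.1 CPM; no sort or gate that would remove such cells is given in the sources used here. A lower share of fibroblasts that raises every other cell type alike was argued against, since the lower of the endothelial and epithelial medians was -2.192. BI-2536 removes dividing cells of any type, so this test cannot decide on a loss of several dividing cell types together. The choice among 3 scalings was argued against too, since the lowest median of the macrophage list over them was 4.271. They moved the median of all genes only from 0.001 to 0.098, so an error common to all 3 was not tested. A candidate source is macrophages among the senescent cells. The list of 48 further leukocyte genes was chosen after values were seen, so its share cannot decide this. Of them, 93.8% were higher in n-Sen, against 6553 of all 19264 genes tested. Arhgdib, Syk and Runx3 were lower, from levels of 245.3, 44.65 and 3.755 CPM in proliferating cultures. The macrophage hypothesis stays open beside expression of the marker and leukocyte genes by senescent fibroblasts themselves, which was not tested. Proliferating cultures also held these marker and leukocyte transcripts, mostly at a low level. Of the 20 markers and 48 leukocyte genes, 15 and 19 lay at 1 CPM or more and 2 and 3 at 10 CPM or more. In addition, 2 of the markers are also in the lysosome list.

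Distal Hox genes, seen first and then tested, rose in n-Sen cells: of 11 tested genes of paralog groups 10 to 13, 10 were higher and 0 lower (median 4.36), with Hoxc13 at 11.9 ± 1.71 against 0.486 ± 0.00191 CPM and Hoxa13 at 6.32 ± 0.578 against 0.102 ± 0.144 CPM. A rise of all Hox groups alike was argued against, because groups 1 to 9 had a median of -0.11 over 25 genes, 8 higher and 6 lower, with an upper quartile of 0.45. Whether groups 1 to 9 were silent in proliferating cells was not examined. A loss of silencing that can raise only silent genes therefore stays open. Cells of another body region may make up more of the senescent cultures, since 2 of 2 hindlimb genes, Tbx4 and Pitx1, rose with them by 2.97 ± 0.155 and 2.15 ± 0.097, but these genes could also rise within the same cells, so the explanation stays open.

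Targets of the aryl hydrocarbon receptor (AhR battery), one of which, Nqo1, is also an NRF2 target, fell in alkaline medium together with NRF2 targets. The 5 battery genes, picked after their values were seen, were each lower in alkaline than in control medium, whose libraries lie in one table. The choice among 3 scalings was argued against, since the highest median over them was -1.398. They kept the median of all genes between -0.019 and -0.004, so an error common to all 3 was not tested. That the control libraries carry the raised level may account for part of the pattern: the battery median was 1.967 in control medium against n-Sen, -1.404 in alkaline against control medium and 0.573 in alkaline medium against n-Sen, but the latter and the first compare separate tables and cannot be told apart from a difference between them. The contrasts also share the control libraries with opposite signs, so part of their opposite moves may come from these libraries, and no value for unchanged groups was computed. Of the NRF2 targets, 20 of 28 were higher in control medium against n-Sen (median 0.46) and 10 higher and 3 lower in alkaline medium against n-Sen (median 0.060). Of 25 cholesterol synthesis genes, 9 were higher and 0 lower in control medium against n-Sen (median 0.051), and 19 were higher in alkaline medium against n-Sen as well as against control medium.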
